A study of Trachemys scripta with 10 samples.

How the data were processed

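Single-cell RNA sequencing of red-eared slider turtle gonads (Trachemys scripta, a species whose sex is set by incubation temperature) was taken from 10 libraries made with the Chromium 3′ kit. Per the labels, each library pooled 100 pairs of gonads. The libraries fall into 3 groups: the common start at stage 15 (1 library), a female-producing temperature arm (FTP, 4 libraries at stages 16, 17, 19 and 21) and a male-producing temperature arm (MTP, 5 libraries at stages 15.5 and 16.5, written 15_5 and 16_5 as in the titles, 17, 19 and 21). Each stage and temperature has 1 library, so no single stage has a test between the arms. Stages 17, 19 and 21 were sampled in both arms, and stages of the same number were taken as matched.

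The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, already limited to cell-containing barcodes by the authors. The submitters' notes name Cell Ranger 4.0.0 and Seurat 4.3.0.1, whereas the matrices name Cell Ranger 6.1.1 per the file headers. The sources used here do not give the genome build. Of 21172 gene identifiers, 21133 matched the RefSeq gene table. A symbol was shared with another identifier for 1654 identifiers, and 3007 carry only a locus number as their name. FOXL2 is the symbol of 2 features: gene 117882884, called FOXL2 here, and gene 117867894, named LOC117867894 in RefSeq. Trachemys CYP19A1, named so in the count files, is a locus number in RefSeq.

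Cells needed at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, from 37 mitochondrial genes. Of 131205 barcodes, 57766 passed. Doublets were called per library against simulated pairs of cells (2 per cell) by the share of simulated profiles among nearest neighbours, at a rate of 0.8% per 1000 barcodes, which gave 4.39 to 14.6%. Removing 6807 doublets left 50959 cells. All libraries were clustered together on log counts scaled to 10000 UMIs per cell, 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0, which gave 41 clusters (24 at resolution 0.5). Genes of the male pathway, female pathway, cold-inducible, heat shock and thermosensitive lists, and mitochondrial and ribosomal genes, were kept out of the clustering. A cluster was named when at least 3 markers of 1 of 14 cell type lists exceeded the other clusters by a log2 fold of 1. The markers had to be detected in 10% of its cells, with a margin of 2 markers over the next list. Clusters with at least 95% of cells from 1 library stayed unnamed. So did clusters with median UMIs under 1/3 of the library median and no own marker among their 10 leading genes. In all 11 clusters stayed unnamed, of which clusters 20, 28, 37 and 40 met the marker rule. No cluster met the marker rule for surface epithelium. Cluster 10, with 6 supporting and 5 surface epithelium markers, was therefore compared under its number in place of that class. Its 10 leading genes include 2 supporting markers.

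UMIs were summed per library and class, since libraries and not cells are the replicates. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. MTP was compared with FTP by the edgeR quasi-likelihood F test on the 6 libraries of the matched stages, with stage as a block, TMM scaling and the filterByExpr filter on low counts. The spread in this test comes from how the difference between the arms varies between stages, pooled over genes by the fit, and not from repeated libraries. Divergence of the arms was tested in all 10 libraries as a difference of slopes per stage, with a shared intercept at stage 15. A Benjamini-Hochberg adjusted p under 0.05 is called here, and fold changes are log2 of MTP over FTP with their standard error. For edgeR this error was derived from the test, as the size of the log2 fold over the square root of F. Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over 19 lists.

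Shares of cells carry exact Clopper-Pearson 95% intervals. They were compared by an exact two-sided sign-flip permutation test over 3 stages, whose smallest p is 0.25. Levels are CPM (a gene's UMIs over those of the class in the library, as in edgeR) with exact Poisson 95% intervals. A level of 0 is given with the CPM that 3 UMIs would make. Intervals and floors cover counting error only. For germ and endothelial classes no test was run, because a library held fewer than 50 cells. This limit was not set for the supporting class, which was tested with 24 cells at stage 21 FTP.

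The lists, markers, tests and the rule for naming genes were fixed before the data were examined. The rule names DMRT1, SOX9, AMH, KDM6B, FOXL2 and CYP19A1 in every library, then in supporting cells the 12 genes of lowest p per direction among those called in the same direction at 3 of 3 stages. For other classes and the divergence it names the 6 of lowest p per direction, and for each other list up to 4 members. Genes known by a locus number were left out and counted. Genes named outside this rule are marked as chosen after their values were seen. The alternatives were another scaling, no low-count filter, the DESeq2 Wald test, doublets kept, at least 1500 genes per cell, Leiden resolution 0.5, thinning, no stage block, 9 libraries with a linear stage, stage as its rank, and leaving out each stage pair or library. After seeing the data, a maximum of 20% mitochondrial UMIs, wider and narrower classes were added.

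The tests were checked on simulated counts of the same depth with 200 changed genes. In supporting cells 12% of 2-fold and 68% of 4-fold changes were recovered, in stromal cells 40% and 90%, in cluster 10 33% and 89%, in all cells 25% and 83%, and for the divergence 3% and 23% of slopes that reach those folds at stage 21. Of these simulated calls, 2.44 to 4.69% were false.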

Results

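The data are UMI counts per gene and cell from turtle gonads sampled between stages 15 and 21, while the bipotential gonad of both arms becomes an ovary or a testis. The common start at stage 15 is 1 library, the female-producing arm (FTP) 4 and the male-producing arm (MTP) 5, each from pooled gonads and without a repeat at its stage. Total UMIs were 177263687 at stage 15. In FTP they were 139836029 at stage 16, 127423055 at stage 17, 41297655 at stage 19 and 55212239 at stage 21. In MTP they were 114816546 at stage 15_5, 142933821 at stage 16_5, 55080598 at stage 17, 110430052 at stage 19 and 135960698 at stage 21. Kept cells ranged from 2739 (stage 17 MTP) to 8061 (stage 15), and median UMIs per kept cell from 2336 (stage 16_5 MTP) to 14793 (stage 17 MTP). The share of barcodes that passed the cell filters ranged from 24.1% at stage 15_5 MTP to 59.5% at stage 15.

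Which cells the gonads held, and whether their shares differ between the arms, was asked first. Supporting-class cells, the lineage that forms Sertoli or granulosa cells, made up 15.3% of the cells at stage 15 (95% Clopper-Pearson interval 14.5 to 16.1). In FTP their share was 36.1% at stage 16, 6.61% at stage 17, 2.01% at stage 19 and 0.730% at stage 21, where 24 cells remained. In MTP it was 47.4% at stage 15_5, 12.7% at stage 16_5, 7.85% at stage 17, 8.94% at stage 19 and 16.0% at stage 21. Germ cells made up 9.10% of the cells at stage 21 FTP (8.13 to 10.1) and 1.55% at stage 21 MTP (1.29 to 1.85). The supporting share was higher in MTP at 3 of 3 matched stages and the germ share lower at 3 of 3, with an exact sign-flip p of 0.25 for each, the smallest p that 3 stages allow. The difference in mean logit was 1.66 for supporting and -1.18 for germ cells. For supporting cells it was 0.37 at Leiden resolution 0.5, 0.87 without stage 21 and 2.40 without stage 17. The germ class held 14 cells at stage 17 FTP and 2 at stage 17 MTP. At stage 19 it held 41 of 2788 cells in FTP and 50 of 5837 in MTP, where 33 more cells with 6 germ markers formed cluster 40, seen in that library alone and left out of the classes.

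The other classes also differed from library to library. Cluster 10, whose markers fit supporting cells (6) and surface epithelium (5) about alike, held 6.07, 5.77 and 5.75% of cells at stages 17, 19 and 21 in FTP and 5.07, 2.66 and 3.11% in MTP (exact sign-flip p = 0.25, lower in MTP at 3 of 3 stages; p = 0.5 among cells outside the erythroid class). The stromal class held 44.5, 28.1 and 7.48% in FTP and 34.8, 15.8 and 13.9% in MTP (exact p = 0.75). Stromal, endothelial and immune differences of -0.15, -0.18 and 0.03 in logit changed sign when a stage pair was left out: stromal to 0.14 without stage 19, endothelial to 0.01 without stage 17 and 0.23 without stage 19, and immune to -0.04 without stage 21. Mesonephric tubule cells differed by -1.29 (exact p = 0.25, lower in MTP at 3 of 3 stages), or by -0.49 without stage 21, and among cells outside the erythroid class 1 of 3 stages was higher in MTP (exact p = 0.5). Red blood cells ranged from 4.48% of cells at stage 16 FTP to 62.9% at stage 21 FTP. Unnamed clusters other than number 10 held 51.2% of cells at stage 16_5 MTP and 22.2% at stage 19 MTP. With the neighbouring clusters of supporting or epithelial markers added to the supporting class, stages 17, 19 and 21 had 12.8, 8.82 and 10.7% in FTP and 13, 12.5 and 20.5% in MTP.

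**Figure D1:**
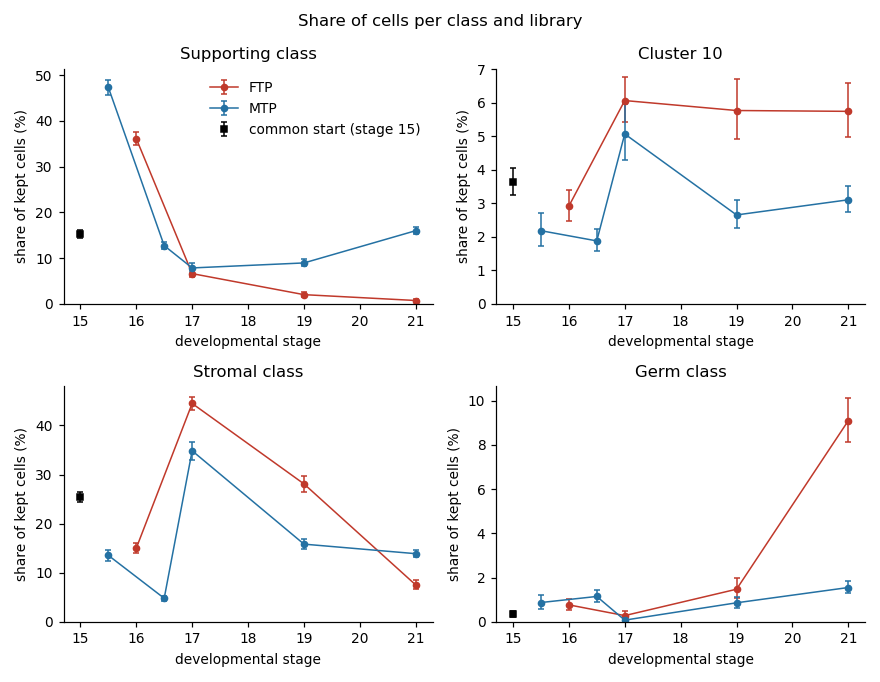
Share of kept cells (%, y axis) by developmental stage (x axis) for 4 cell classes, 1 point per library in FTP (red), MTP (blue) and at the common start (black), with exact 95% Clopper-Pearson bars. At stage 21 the supporting class held 0.730% of cells in FTP and 16.0% in MTP, and the germ class 9.10 and 1.55%.

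Key genes of sex determination were then followed through the supporting class. DMRT1, SOX9, AMH and FOXL2 were kept out of the clustering but are among the markers that name this class. Cluster 11, for one, was named by 8 supporting markers, AMH and DMRT1 among them. The name of the class is therefore not independent of these genes. DMRT1, a transcription factor of the male pathway, stood at 76.5 CPM at stage 15 and was near 18 CPM in FTP at stages 16, 17 and 19 (18.1, 18.2 and 17.6 CPM). In MTP it was 20.2 CPM at stage 15_5, 38.8 at stage 16_5, 93.4 at stage 17, 103.5 at stage 19 and 79.0 at stage 21. AMH, the hormone that removes the Müllerian ducts in males, was 10.8, 45.4 and 72.0 CPM at stages 17, 19 and 21 in MTP. In FTP it was 1.87 CPM (4 UMIs) at stage 17 and 0 at stages 19 and 21, where 3 UMIs would make 8.79 and 36.1 CPM, so that AMH was at least 5.17-fold higher in MTP at stage 19 and at least 1.99-fold higher at stage 21. FOXL2, a transcription factor of granulosa cells, was 16.8, 23.4, 32.2 and 120.3 CPM at stages 16, 17, 19 and 21 in FTP. In MTP it was 5.40, 1.45 and 0.152 CPM at stages 17, 19 and 21. CYP19A1, the aromatase that makes oestrogens, was 5.86 CPM (2 UMIs) at stage 19 FTP and 349 CPM (29 UMIs) at stage 21 FTP, and 0 in all 5 MTP libraries.

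Across the matched stages DMRT1 rose in MTP over FTP by 2.45 ± 0.36 on the log2 scale (edgeR adjusted p = 8.4e-06) and AMH by 3.63 ± 0.63 (edgeR adjusted p = 1.6e-04), each at 3 of 3 stages. FOXL2 fell by 4.63 ± 0.73 (edgeR adjusted p = 3.4e-05, 3 of 3 stages). At stage 21 FOXL2 had 10 UMIs in FTP and 1 in MTP, a ratio of 792 with a counting interval of 113 to 34376. CYP19A1 fell (edgeR adjusted p = 8.6e-08, lower at 2 stages and 0 in both arms at stage 17). Against the 0.456 CPM that 3 UMIs would make at stage 21 MTP it was at least 766-fold lower there. SOX9, a transcription factor of Sertoli cells, did not pass (0.94 ± 0.41, edgeR adjusted p = 0.285). It was 33.6, 11.7 and 0 CPM at stages 17, 19 and 21 in FTP and 48.6, 30.9 and 31.6 CPM in MTP, and the floor at stage 21 FTP was 36.1 CPM. KDM6B, a demethylase of histone H3, did not pass either (0.31 ± 0.27, edgeR adjusted p = 0.748), with 132, 179 and 120.3 CPM in FTP and 212, 147 and 140.2 CPM in MTP.

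Some of these calls depend on where the class ends. At Leiden resolution 0.5, where clusters such as number 10 join the supporting class, DMRT1, AMH and FOXL2 lost their calls (edgeR adjusted p = 0.161, 0.161 and 0.204) with log2 folds of 3.36 ± 0.48, 5.68 ± 0.90 and -3.95 ± 0.77. The folds of DMRT1 and AMH were larger there than in the main fit, so their lost calls do not show smaller differences. Over 13 alternatives the adjusted p ranged from 1.3e-08 to 0.161 for DMRT1, from 3.3e-15 to 0.161 for AMH and from 7.0e-14 to 0.204 for FOXL2, the highest values being those at resolution 0.5. DMRT1 and AMH kept their calls in 10 of the 13 and FOXL2 in 11: all 3 also lost them with the neighbouring clusters added, and DMRT1 and AMH with 9 libraries and a linear stage. CYP19A1 lost its call by DESeq2 (adjusted p = 0.774, range from 2.2e-15 over 6 alternatives).

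**Figure D2:**
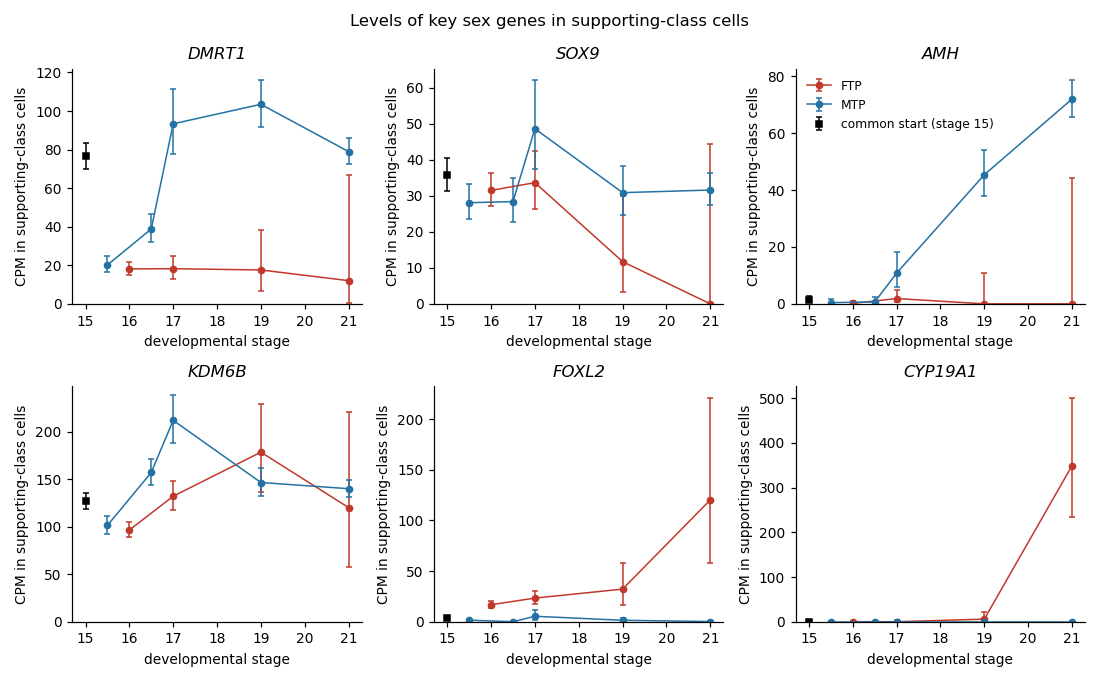
CPM of 6 sex genes in supporting-class cells (y axis) by developmental stage (x axis), 1 point per library in FTP (red), MTP (blue) and at the common start (black), with exact 95% Poisson bars for counting error. At stage 21 AMH stood at 72.0 CPM in MTP and 0 in FTP, and CYP19A1 at 349 CPM in FTP and 0 in MTP.

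Over all genes, the arms of the supporting class were compared to find what else differs between them. Whether the FTP cells of this class are future granulosa cells was not tested. MAP7D2, a microtubule-associated protein, rose by 4.44 ± 0.57 (log2), SYNE2, a nuclear envelope protein, by 3.07 ± 0.40, and CLDN11, a tight junction protein of Sertoli cells, by 2.56 ± 0.33. COL2A1 and COL8A1, collagen chains, rose by 2.31 ± 0.31 and 2.85 ± 0.41. GFRA3, a receptor of the GDNF family, rose by 2.26 ± 0.30, NTS, the precursor of neurotensin, by 3.03 ± 0.41, and SCD, which makes monounsaturated fatty acids, by 2.48 ± 0.36. FGL1, a secreted protein, rose by 4.98 ± 0.71, BCAS1 by 2.84 ± 0.40 and RRAD, a small GTPase, by 2.17 ± 0.32. With DMRT1 these are the 12 named genes that rose, each at 3 of 3 stages, with edgeR adjusted p from 8.3e-07 (MAP7D2) to 8.5e-06 (SCD). At stage 21 FTP, where 3 UMIs would make 36.1 CPM, MAP7D2, NTS, BCAS1, FGL1 and COL8A1 stood at 0. MAP7D2 and FGL1 were 0 at stage 19 FTP too, and 1.87 and 0.93 CPM at stage 17 FTP, so their folds rest on few FTP UMIs.

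Other genes were lower in MTP, and so higher in FTP. FBLN5 and MFAP2, proteins of elastic fibres and microfibrils, fell by 6.44 ± 0.79 and 3.71 ± 0.41 on the log2 scale. GLDN, an adhesion protein, fell by 6.07 ± 0.72, AVIL, an actin-binding protein, fell by 5.25 ± 0.72, and TACR1, the receptor of substance P, by 3.42 ± 0.50. ECRG4, a secreted peptide precursor, fell by 3.88 ± 0.38. S100A7, a calcium-binding protein, fell by 5.14 ± 0.53. BAG3, a partner of HSP70, fell by 2.87 ± 0.32, HSPB6, a small heat shock protein, by 3.16 ± 0.45, and OTUD1, a deubiquitinase, by 2.16 ± 0.30. BAG3 was not particular to this class: it was lower in MTP at 3 of 3 stages in stromal cells (-2.44 ± 0.36), cluster 10 (-2.10 ± 0.34), endothelial and immune cells. In stromal cells and cluster 10 it had no call (edgeR adjusted p = 0.064 and 0.434), and in germ and erythroid cells it was higher in MTP at 1 stage. COL1A2 and COL1A1, collagen chains that also served as stromal markers, fell by 2.56 ± 0.32 and 1.92 ± 0.29. All 12 fell at 3 of 3 stages, with edgeR adjusted p from 2.3e-09 (ECRG4) to 2.1e-05 (COL1A1). At stages 17, 19 and 21 in MTP, FBLN5 stood at 0, 0.36 and 1.06 CPM and AVIL at 0, 0.73 and 1.97 CPM. GLDN stood there at 3.09, 0.36 and 1.06 CPM, so the folds of these 3 genes rest on few MTP UMIs. S100A7 changed sign when these clusters joined the class, to 0.04 at resolution 0.5 and 0.26 with the neighbouring clusters added.

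In total 323 of 9875 genes passed in edgeR, 160 higher and 163 lower in MTP, of which 155 and 153 kept their direction at 3 of 3 stages and 3 and 9 are known by a locus number. Of the 160 and 163, 79 and 109 were among the variable genes used for clustering. Those calls are therefore not independent of how the class was drawn. At an unadjusted p under 0.05 there were 1259. The DESeq2 Wald test called 158, of which 157 were among the 323. No gene passed at resolution 0.5 or with the neighbouring clusters added, where 1787 and 1834 had an unadjusted p under 0.05, although 309 and 310 of 322 tested calls kept their direction with median ratios of 0.64 and 0.65 of the log2 fold. Without stage 19 there were 102 calls, without a stage block 137, with 9 libraries 30, with counts thinned to the smallest total 30 of 1622 genes, and with up to 20% mitochondrial UMIs 643. The supporting cells of stages 19 and 21 MTP lay mostly in 1 cluster (447 of 522 and 1254 of 1261 cells), which held 4 of 24 cells at stage 21 FTP. HBAA, a haemoglobin gene of red blood cells, stood in this class at 3423, 3705 and 987 CPM at stages 17, 19 and 21 in FTP and at 2619, 8089 and 20503 CPM in MTP.

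**Figure D3:**
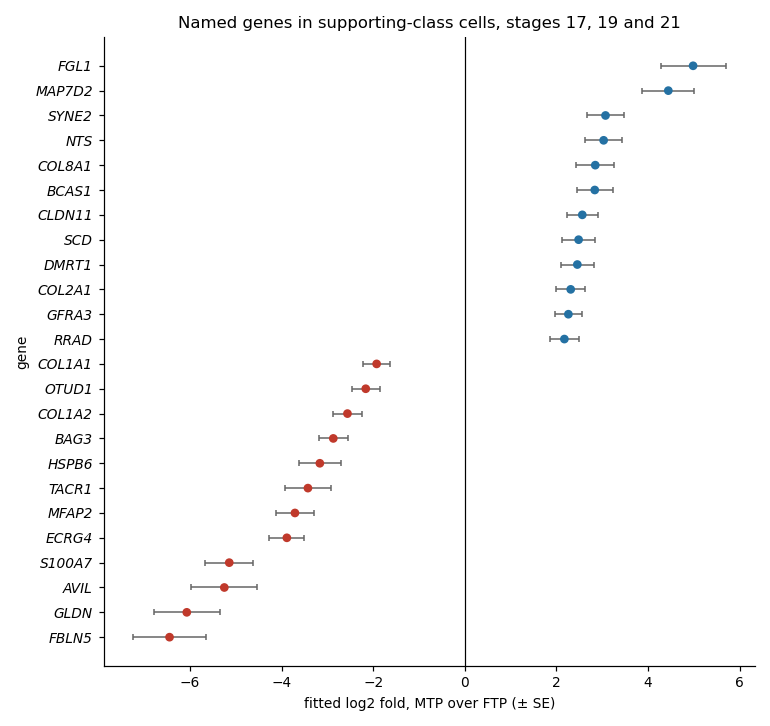
Fitted log2 fold of MTP over FTP (x axis, points, with SE bars) for the 24 named genes in supporting-class cells of stages 17, 19 and 21 (y axis). Folds ranged from -6.44 (FBLN5) to 4.98 (FGL1).

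The 2 lists of sex genes moved in opposite directions. Both share members with the markers that name the supporting class, among them DMRT1, AMH, INHBB and FOXL2. Of 16 measured members of the male pathway, 3 rose in MTP (CLDN11, DMRT1 and AMH) and 0 fell, or 5 and 0 adjusted over the list alone, which adds PDGFA, a growth factor (0.85 ± 0.31), and INHBB, an activin subunit (0.82 ± 0.31). Of 15 measured members of the female pathway 6 fell and 0 rose, and 6 and 0 adjusted over the list alone. Beside FOXL2 and CYP19A1 these were TWIST1, a mesenchymal transcription factor (-2.56 ± 0.41), AXIN2, a target of WNT signalling (-2.64 ± 0.54), HSD17B1, an enzyme of oestradiol synthesis (-1.60 ± 0.33), and GREB1, an oestrogen-responsive gene (-1.66 ± 0.39). By camera the male list was higher in MTP (adjusted p = 3.0e-05) and the female list lower (adjusted p = 3.7e-05). Neither was called with an estimated correlation (adjusted p = 0.295 for each). HBAA was higher in MTP at stages 19 and 21 beside both lists. The stromal markers COL1A2 (-2.56 ± 0.32) and COL1A1 (-1.92 ± 0.29) and the dissociation stress list (camera adjusted p = 1.1e-12) were lower in MTP, as the female list was.

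Signalling and stress lists were mostly lower in MTP. Of 15 WNT members 2 fell, AXIN2 and TCF7L2 (-1.26 ± 0.32), a transcription factor of the pathway, or 3 adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.350 with an estimated correlation). Of 9 hedgehog members 1 fell, CDON, a co-receptor (-1.13 ± 0.30), and 1 adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.295 with an estimated correlation). Of 9 NOTCH members 1 fell, HES1, a repressor downstream of the receptors (-1.06 ± 0.27), or 2 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.295 with an estimated correlation). Of 29 members of the TGF-beta, BMP and activin list 3 fell, the helix-loop-helix inhibitors ID1, ID2 and ID3 (-1.22 ± 0.28, -1.34 ± 0.35 and -1.54 ± 0.26), and 2 rose, AMH and TGFB3 (1.71 ± 0.47), or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0267, down; adjusted p = 0.295 with an estimated correlation). Of 21 dissociation stress genes 8 fell, among them FOSB (-2.20 ± 0.35), ATF3 (-1.84 ± 0.37), CCN1 (-1.50 ± 0.27) and FOS (-1.29 ± 0.26), immediate early genes, and 15 fell adjusted over the list alone (camera adjusted p = 1.1e-12; adjusted p = 0.295 with an estimated correlation).

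Of 19 measured cell cycle genes none passed alone in edgeR, nor adjusted over the list alone. As a list they were higher in MTP by camera (adjusted p = 0.0136; adjusted p = 0.295 with an estimated correlation), 17 with positive and 2 with negative folds, such as CCNB1, a cyclin of mitosis (2.14 ± 0.86), and TPX2, a spindle protein (1.19 ± 0.47). Cycling cells outside the class went both ways. Cluster 14, with 2 supporting markers, held 0.83, 0.29 and 0.58% of cells at stages 17, 19 and 21 in FTP and 0.51, 0.24 and 0.05% in MTP. Cluster 37, with 8 supporting markers and CCNB1 among its leading genes, held 0 cells at these stages in FTP and 1, 40 and 103 in MTP. In all, camera called 8 of 19 lists, 0 with an estimated correlation, 3 without stage 17 (male pathway, female pathway and dissociation stress) and 4 without stage 19 (these and WNT signalling).

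The remaining lists were not called by camera. Heat shock chaperones went both ways: of 23 measured, CRYAB (2.76 ± 0.46), HSP90B1 (1.22 ± 0.28) and DNAJC3 (1.15 ± 0.33) rose, and BAG3, HSP90AA1 (-1.41 ± 0.26), HSPA2 (-1.33 ± 0.26) and SERPINH1 (-1.30 ± 0.33) fell, with 4 up and 4 down adjusted over the list alone. Their median was 0.04 and their mean -0.02, and camera's direction was down (adjusted p = 0.546). For the cold-inducible list the median was 0.02, the mean -0.03 and camera's direction down (16 measured, adjusted p = 0.627), and CIRBP alone fell, also adjusted over the list alone. Of 11 steroidogenesis genes CYP19A1 and HSD17B1 fell, and adjusted over the list alone FDXR (1.79 ± 0.59) and STAR (2.17 ± 0.71) were added on the higher side. Their median was 0.43 and their mean -0.59, or -0.44 with CYP19A1 at its bound of -9.58, and camera's direction was up (adjusted p = 0.648). Of 16 basement membrane genes COL18A1 (1.70 ± 0.29) and LAMA1 (1.37 ± 0.33), matrix proteins, rose, or 5 adjusted over the list alone (camera adjusted p = 0.0877). Of 10 junction genes 2 rose, CLDN11 among them, or 3 adjusted over the list alone, and as a list they were not called (camera adjusted p = 0.499).

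Among 20 glycolysis and hypoxia genes EGLN3, an oxygen-sensing hydroxylase, fell (-1.07 ± 0.31), or 2 adjusted over the list alone (camera adjusted p = 0.0662). Of 23 oxidative phosphorylation genes none passed and NDUFA1 (0.91 ± 0.27) did adjusted over the list alone (camera adjusted p = 0.221). Of 9 retinoic acid genes none passed, and ALDH1A1 (0.98 ± 0.34) and CRABP1 (0.99 ± 0.36) did adjusted over the list alone (camera adjusted p = 0.786). No member passed, nor adjusted over the list alone, among 20 thermosensitive channel and calcium-redox genes (camera adjusted p = 0.423; PRDX1 0.71 ± 0.27), 26 chromatin regulators (camera adjusted p = 0.546; TET3 -0.76 ± 0.33) or the 2 measured meiosis genes (camera adjusted p = 0.546; SYCP3 -0.82 ± 0.88).

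CIRBP, a cold-inducible RNA-binding protein, was lower in MTP in each class followed. In supporting cells it fell by 1.64 ± 0.27 on the log2 scale (edgeR adjusted p = 6.0e-05). It stood there at 1025 CPM at stage 15, at 3786, 2689, 1708 and 1949 CPM at stages 16, 17, 19 and 21 in FTP, and at 1527, 2078, 854, 502 and 523 CPM at stages 15_5, 16_5, 17, 19 and 21 in MTP. In stromal cells, cluster 10 and all cells together the log2 folds were -1.52 ± 0.29, -1.41 ± 0.24 and -1.18 ± 0.19, without a call (edgeR adjusted p = 0.123, 0.441 and 0.389). CPM were lower in MTP at 3 of 3 stages, with separate counting intervals, in supporting, stromal, cluster 10, germ, endothelial, immune and erythroid cells. At stage 21 endothelial cells held 981 CPM in FTP and 203 in MTP, and immune cells 439 and 244. The supporting call held in 11 of 14 alternatives (adjusted p from 1.1e-08 to 0.161) and ended at resolution 0.5 (log2 -1.48, adjusted p = 0.161), with the neighbouring clusters added, and with 9 libraries and a linear stage.

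**Figure D4:**
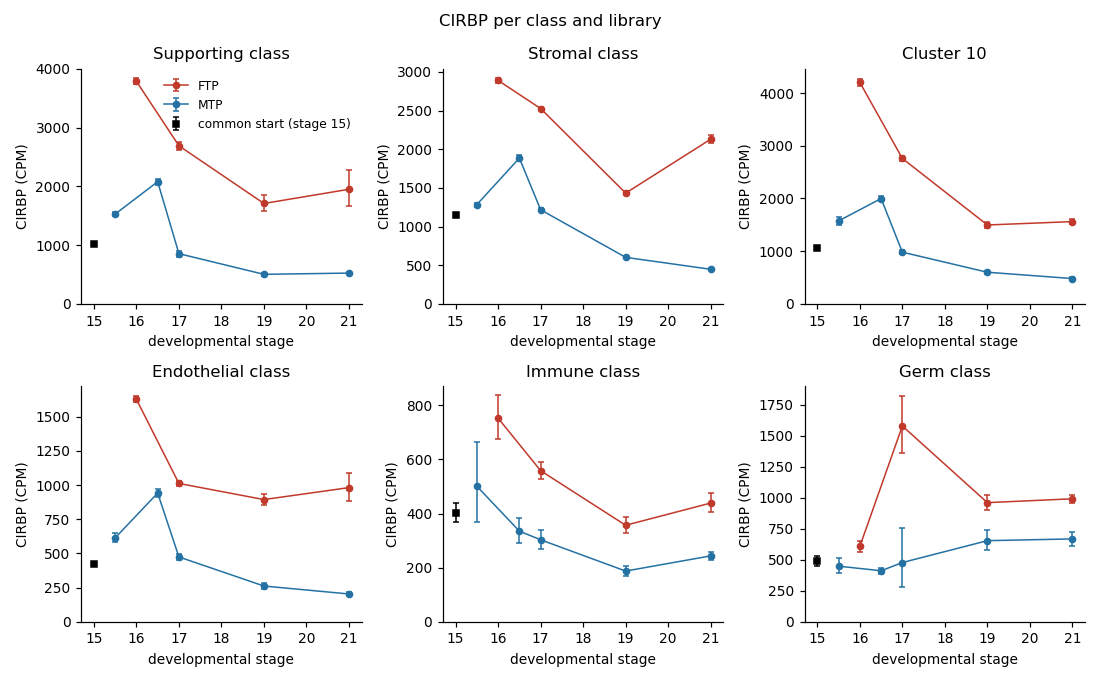
CPM of CIRBP (y axis) by developmental stage (x axis) in 6 classes, 1 point per library in FTP (red), MTP (blue) and at the common start (black), with exact 95% Poisson bars for counting error. At stages 17, 19 and 21 the FTP library lies above the MTP library in each class.

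In stromal cells, the mesenchyme between the forming cords, the called genes were lower in MTP. PTHLH, a parathyroid hormone-like peptide, fell by 3.59 ± 0.24 on the log2 scale and stood at 186 CPM at stage 21 FTP and 15.9 CPM at stage 21 MTP. PI16, a marker of fibroblasts, fell by 4.36 ± 0.39, KCNE4, a potassium channel subunit, by 2.38 ± 0.21, and ITGA6, a laminin receptor subunit, by 2.65 ± 0.25. ETNPPL, an enzyme of phosphoethanolamine breakdown, fell by 6.42 ± 0.60 and AHSA2, a partner of HSP90, by 2.56 ± 0.24. These 6 passed with edgeR adjusted p from 0.0026 (PTHLH) to 0.0086 (ITGA6), lower at 3 of 3 stages. PI16 stood at 0.03 CPM in FTP and 0 in MTP at stage 17, and at 1.23 and 0.07 CPM at stage 19. ETNPPL stood at 0.15, 0.13 and 0.16 CPM at stages 17, 19 and 21 in MTP. PI16 at stages 17 and 19 and ETNPPL in MTP therefore rest on few UMIs. In total 12 of 12909 genes passed, all lower in MTP, 1 of them known by a locus number, and 1562 had an unadjusted p under 0.05. Of the 12, 8 were among the variable genes used for clustering. The class lay in different clusters in the 2 arms: at stage 19 cluster 31 held 429 of 783 stromal cells in FTP and cluster 1 held 715 of 923 in MTP, and at stage 21 cluster 16 held 67 of 246 in FTP and 1009 of 1093 in MTP. DESeq2 called 281 genes (49 higher and 232 lower in MTP), edgeR with no low-count filter 678 (196 and 482), and the largest stromal cluster alone 93 (12 and 81). There were 448 calls without stage 17 (122 higher and 326 lower), 8 without stage 19 and 0 without stage 21 (where PTHLH had edgeR adjusted p = 0.0629 and a log2 fold of -3.87), and 5 without stress-led clusters. Dissociation stress genes, a sign of handling, were lower in MTP beside these genes: 11 of 23 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 1.8e-12; adjusted p = 0.597 with an estimated correlation).

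In cluster 10 no gene of 10531 passed in edgeR, with 914 at an unadjusted p under 0.05, 55 by DESeq2, 84 with no low-count filter and 5 without stage 17. The lowest p belonged to WFDC8 (-4.84 ± 0.56), a gene named after its values were seen (edgeR adjusted p = 0.434, lower at 3 of 3 stages). In all cells of a library together, where composition and expression both count, no gene of 15716 passed in edgeR, with 1682 at an unadjusted p under 0.05 and 346 by DESeq2. DMRT1 had the lowest p there (2.49 ± 0.21, edgeR adjusted p = 0.382, higher in MTP at 3 of 3 stages).

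Whether the arms move apart with stage was asked of all 10 libraries in the supporting class. NTS and RRAD parted because they fell in FTP, by 1.13 ± 0.15 and 0.72 ± 0.09 log2 per stage, while their MTP slopes were 0.01 ± 0.07 and 0.01 ± 0.06. SYNE2, COL8A1 and COX5B-2, a respiratory chain subunit, had MTP slopes of 0.64 ± 0.08, 0.47 ± 0.07 and 0.61 ± 0.07 per stage and FTP slopes of -0.25 ± 0.13, -0.42 ± 0.15 and -1.31 ± 0.33. LMO1, a transcriptional cofactor, rose in MTP (0.19 ± 0.06) and fell in FTP (-0.54 ± 0.13). On the other side MFAP2 rose in FTP by 0.55 ± 0.07 per stage and fell in MTP (-0.34 ± 0.07). GLDN, MME (a membrane peptidase), COL1A2 and HSPB6 had FTP slopes of 0.96 ± 0.10, 0.56 ± 0.06, 0.49 ± 0.06 and 0.72 ± 0.09 per stage and MTP slopes of -0.32 ± 0.11, -0.01 ± 0.06, -0.13 ± 0.07 and -0.04 ± 0.08, and CYP19A1 rose in FTP too, from 0 UMIs at stage 15 to 29 at stage 21. These 12 differed between the arms with edgeR adjusted p from 2.2e-05 (MFAP2) to 0.0026 (LMO1).

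Of the other key genes, DMRT1 diverged by 0.74 ± 0.16 per stage (edgeR adjusted p = 0.0235), AMH by 1.32 ± 0.31 (edgeR adjusted p = 0.0386) and FOXL2 by -1.44 ± 0.21 (edgeR adjusted p = 0.0020), whereas SOX9 (0.29 ± 0.11, edgeR adjusted p = 0.344) and KDM6B (0.07 ± 0.07, edgeR adjusted p = 0.694) did not pass. AMH rose in MTP by 1.15 ± 0.13 per stage (edgeR adjusted p = 7.3e-05). In total 174 of 11145 genes diverged, 82 higher and 92 lower in MTP. Slopes passed for 1343 genes in MTP (698 up, 645 down) and 172 in FTP (91 up, 81 down); the difference of these counts was not tested. At resolution 0.5 the counts were 1622 in MTP and 1551 in FTP, and with the neighbouring clusters added 1502 and 1502. The divergence count fell to 51 without stage 19 FTP, 84 without stage 21 MTP, 90 without stage 21 FTP and 97 without stage 19 MTP. The MTP count was 240 without stage 21 MTP and 658 without stage 19 MTP. The FTP count was 352 without stage 15, 90 without stage 17 FTP, 32 without stage 19 FTP, 86 without stage 21 FTP, 113 without stage 15_5 MTP and 93 without stage 16_5 MTP. At resolution 0.5 there were 559 divergence calls, 103 of them shared, but MME, COL1A2 and HSPB6 lost theirs. The CYP19A1 divergence lost its call without stage 21 MTP (edgeR adjusted p = 0.117) and by DESeq2 (adjusted p = 0.120), the others of its 13 alternatives ranging from 1.7e-05.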

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

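The tests of explanations for the supporting share and for LOC117867894 were chosen only after the results were seen, apart from the sign-flip test of shares; the 20% mitochondrial filter was added after seeing the data, with bounds set before its own result. Of 34 groups of 4 to 10 libraries examined for a library far from the others, 10 stood out. Chance alone marks about 1 in 20 groups of like libraries, but these groups span different stages. A change with stage can mark a library too, so the 10 are not read as an excess.

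The supporting class took 36.1% of the cells at stage 16 FTP and 47.4% at stage 15_5 MTP, each far above the other libraries of its arm, and fell to 0.730% at stage 21 FTP. The mitochondrial filter was argued against, since with up to 20% mitochondrial UMIs the stage 21 share was still 26.8-fold higher in MTP. Whether FTP supporting cells were counted under other clusters stays open. At stage 21 FTP 91.5% of the FOXL2 UMIs lay outside the supporting class, but that class held 0.195% of the library's UMIs, so most genes would lie outside it. FOXL2 stood there at 120.3 CPM in the class and 29.7 CPM in cluster 10. That cluster held 67 of the 118 FOXL2 UMIs at stage 21 FTP and 1 of 7 at stage 21 MTP. With the neighbouring clusters added, the stage 21 share was 10.7% in FTP and 20.5% in MTP, so its size depends on where the class ends. The temperature arm stays open: with 1 library per stage and arm the exact sign-flip p was 0.25, the smallest that 3 stages can give, so an effect of the arm cannot be told apart from differences between single libraries.

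LOC117867894, which the count files also label FOXL2, was outside the planned comparisons and stood at 345 CPM in germ cells of stage 21 FTP, against 10.5 CPM at stage 15, and 98.4% of its 1455 UMIs in that library lay in the germ class. It was 104.7 CPM at stage 19 FTP, 7.27 CPM at stage 19 MTP and 16.2 CPM at stage 21 MTP, while stage 17 went the other way, with 8.36 CPM (1 UMI) in FTP and 53.1 CPM (2 UMIs) in MTP. RNA from other cells or doublets was argued against, as no other cluster with at least 20 cells in the stage 21 FTP library exceeded 3.83 CPM (smaller ones reached 11.9 CPM, on 1 UMI), and so were reads shared with FOXL2, which stood at 1.93 CPM in the same germ cells. The temperature arm may underlie the 21.3-fold ratio of FTP to MTP at stage 21, but with 1 library on each side it cannot be told apart from a difference between single libraries. In RefSeq the gene lies between TMEM201 and PIK3CD, whereas FOXL2 lies beside MRPS22.

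Other libraries that stood apart were the germ share at stage 21 FTP (9.10%) and the share of cluster 10 at stage 16 FTP (2.92%). In supporting cells these were FOXL2 at stage 21 FTP (120.3 CPM, 10 UMIs) and at stage 17 MTP (5.40 CPM, 7 UMIs), CYP19A1 at stage 21 FTP (349 CPM), DMRT1 at stage 21 FTP (12 CPM, 1 UMI), SOX9 at stage 17 MTP (48.6 CPM) and AMH at stage 17 FTP (1.87 CPM, 4 UMIs).

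Among 500 pairs of a gene and another class compared, 5 genes called in supporting cells moved the opposite way at 3 of 3 stages in another class; the difference between the classes was not tested. AXIN2 had log2 folds of -2.64 in supporting and 0.42 in stromal cells (edgeR adjusted p = 0.0014 and 0.533). CRYAB, a small heat shock protein, had 2.76 and -3.09 in the same classes (edgeR adjusted p = 8.0e-05 and 0.0955). CDON had -1.13 and 0.68 (edgeR adjusted p = 0.0219 and 0.337). LAMA1 had 1.37 in supporting cells and -1.43 in cluster 10 (edgeR adjusted p = 0.0082 and 0.495), and ID1 had -1.22 and 0.55 there (edgeR adjusted p = 0.0061 and 0.604).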

How the results depend on the processing

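The tests with the 20% mitochondrial maximum, the wider supporting class and the narrower stromal classes, and the counts over other splits of the libraries, were chosen only after the results were seen. Other scaling and doublets kept left each count of genes past the threshold within 1.5-fold, with the 323 supporting calls at 356 and 326. Alternatives for germ and endothelial tests were not run, as those tests were not. Where a count moved, the cause was not tested, except that thinning leaves fewer genes (1622) to test.

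In supporting cells, the 323 genes became 158 by DESeq2, 137 without the stage block, 30 with 9 libraries, 30 after thinning, 0 at Leiden resolution 0.5 and 0 with the neighbouring clusters added (edgeR, 1787 and 1834 at an unadjusted p under 0.05; DESeq2 was not run on these), and 643 with up to 20% mitochondrial UMIs, and from 102 (without stage 19) to 413 (without stage 17) on leaving out a stage pair. All tested calls kept their direction under each of these except resolution 0.5 (309 of 322) and the wider class (310 of 322). The 12 stromal genes became 678 with no low-count filter, 281 by DESeq2, 93 in the largest stromal cluster, 5 without stress-led clusters, and 0 (without stage 21) to 448 (without stage 17). The 0 of cluster 10 (edgeR, 914 at an unadjusted p under 0.05) became 84 with no filter, 55 by DESeq2, and 0 to 5 on leaving out a stage pair. The 0 of all cells (edgeR, 1682 at an unadjusted p under 0.05) became 346 by DESeq2.

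The 174 divergence calls became 273 with no filter, 381 by DESeq2, 559 at resolution 0.5, 443 with up to 20% mitochondrial UMIs, 526 with the wider class, and 51 (without stage 19 FTP) to 246 (without stage 15_5 MTP). The 1343 MTP slopes became 872 with stage as its rank, 2372 with up to 20% mitochondrial UMIs, and 240 (without stage 21 MTP) to 1741 (without stage 15). The 172 FTP slopes became 267 with no filter, 440 by DESeq2, 1551 at resolution 0.5, 105 with stage as its rank, 350 with up to 20% mitochondrial UMIs, 1502 with the wider class, and 32 (without stage 19 FTP) to 352 (without stage 15). The 8 lists called became 0 with an estimated correlation and 3 (without stage 17) to 9 (without stage 21).

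The stromal share difference, -0.15 in logit, turned to 0.19 with at least 1500 genes per cell and ranged from -0.57 (without stage 21) to 0.14 (without stage 19). The endothelial one, -0.18, turned to 0.0658 with up to 20% mitochondrial UMIs and ranged from -0.78 (without stage 21) to 0.23 (without stage 19), with 0.01 without stage 17. The immune one, 0.03, turned to -0.0498 with at least 1500 genes and ranged from -0.0380 (without stage 21) to 0.11 (without stage 17). S100A7 in supporting cells turned from -5.14 to 0.26 with the wider class and 0.0444 at resolution 0.5. Of the other supporting results at matched stages, 870 kept their side of the threshold, 196 lost their call, 32 gained one, and 110 of genes without a call moved by more than their standard error. SOX9 ranged from -0.01 to 1.93 and KDM6B from -0.49 to 0.59 without a call. Stromal results came to 690, 13, 90 and 114, those of cluster 10 to 572, 0, 22 and 75. Depth limits how many genes can be tested: thinned to the smallest total, the 83112 UMIs of stage 21 FTP, 1622 supporting genes were tested in place of 9875.

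Splits of the 6 matched libraries number 10, too few for a share under 0.05: the real split called 323 supporting genes and the highest other 0, 12 and 0 stromal genes, 0 and 25 in cluster 10 and 0 and 0 in all cells. For the divergence, 2 of 100 splits drawn from 126, the real one included, gave 174 or more genes, a share under 0.05. These splits exchanged libraries of different stages, each without a repeat. They therefore cannot tell the arms from differences between single libraries, and chance is not excluded. The highest other, 197, put the FTP label on the stage 16_5, 17, 19 and 21 MTP libraries and so nearly exchanged the arms.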

Other observations

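The list tests outside the supporting class, the germ comparison and the tests of explanations for CIRBP were chosen only after the results were seen. Germ cells were too few for a test and are given as levels, with 1 library per stage and arm and intervals for counting error alone, which do not show an effect of the arm. Genes at 50 CPM or more at stage 21 in either arm numbered 3977, of which 297 were lower and 66 higher in MTP with separate counting intervals at stages 19 and 21. HYI, a sugar isomerase, stood at 947 and 1035 CPM at stages 19 and 21 in FTP and at 165 and 179 CPM in MTP. UNG, a DNA repair glycosylase, stood at 221 and 239.6 CPM in FTP and at 131 and 84.7 CPM in MTP, and BASP1, a membrane-bound cytoskeletal protein, at 92.5 and 314 against 17.0 and 63.5 CPM. Of 19 cell cycle genes in that set 10 were lower in MTP and 0 higher. Of 6 meiosis genes 1 was lower, SYCP2, a part of the synaptonemal complex. STRA8, which starts meiosis, stood at 132 and 144 CPM at stages 19 and 21 in FTP and at 82.4 and 126 CPM in MTP. SYCP3 stood at 122 and 187 CPM in FTP and at 111 and 182 CPM in MTP. Higher in MTP were CRABP1, a retinoic acid carrier (27.0 and 16.6 against 301 and 435 CPM), CLDN11 (0 and 2.65 against 33.9 and 83.4 CPM), which was also higher in MTP in supporting cells, and the matrix genes SPARC (64.6 and 86.9 against 247 and 513 CPM) and DCN (4.36 and 4.82 against 36.4 and 64.7 CPM). HBAA in these germ cells was 3562 and 6199 CPM in FTP and 22658 and 29322 CPM in MTP. CRABP1 was among the leading genes of supporting clusters and HBAA is a gene of red blood cells; the share of RNA from other cells was not computed for germ cells, so these levels are not read as made by germ cells.

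Stromal cells also showed list differences. WNT signalling was lower in MTP by camera (8 of 28 fell adjusted over the list alone and 0 over all genes, adjusted p = 4.5e-06; adjusted p = 0.597 with an estimated correlation), as were heat shock chaperones (1 of 23 fell over all genes and 7 adjusted over the list alone, adjusted p = 1.1e-09; adjusted p = 0.356 with an estimated correlation). Dissociation stress genes, a sign of handling, were lower beside both (camera adjusted p = 1.8e-12). Cluster 31, led by OTUD1, BAG3 and HSPA2, held 429 stromal cells at stage 19 FTP and 11 at stage 19 MTP. Cell cycle genes were higher (0 of 23 passed, adjusted p = 0.0093; adjusted p = 0.597 with an estimated correlation). Beside the 6 named stromal genes, APLNR-A (-2.27 ± 0.22), HSPH1 (-1.65 ± 0.19), DNAJA4 (-1.84 ± 0.22), CXCL14 (-5.91 ± 0.73) and HSPB6 (-1.90 ± 0.24) passed. In all cells together meiosis genes were lower in MTP by camera (0 of 11 passed over all genes and 2 fell adjusted over the list alone, adjusted p = 1.6e-07; adjusted p = 0.669 with an estimated correlation), beside a germ share that was lower in MTP at 3 of 3 stages (exact p = 0.25, the smallest possible). There the male pathway (0 of 20 passed, adjusted p = 0.0015; 0.756 with an estimated correlation), basement membrane (0 of 16, adjusted p = 0.0011; 0.780) and chromatin regulators (0 of 26, adjusted p = 0.0363; 0.669) were higher, and heat shock chaperones (0 of 23, adjusted p = 0.0124; 0.669) and dissociation stress genes (0 of 23, adjusted p = 0.0068; 0.669) lower. The supporting share was higher in MTP beside the male pathway, at 3 of 3 stages (exact sign-flip p = 0.25). In cluster 10 the female pathway was lower (0 of 19 passed over all genes, 2 rose and 5 fell adjusted over the list alone, adjusted p = 0.0344; 0.879 with an estimated correlation).

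CIRBP was lower in MTP in each class followed. Free RNA was argued against as the whole cause: with the free RNA of each library subtracted, the median log2 difference over 4 classes and 3 stages was -1.71, against -1.68 before. Stress-led stromal cells were argued against too, since leaving those clusters out gave -1.61 in stromal cells, against -1.52 with them. The difference passed over 3 stage pairs in supporting cells (edgeR adjusted p = 6.0e-05, lower in MTP at 3 of 3 stages). A response to temperature may underlie this -1.64, but it cannot be told apart from other differences between the arms, such as pace of development or handling, for which the labels give no values. The incubation temperatures are not in the labels either, so the direction was not set against cold induction.

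At stage 21 FTP, 34 of 74 CYP19A1 UMIs lay in germ-class cells (8.19 CPM) and 29 in supporting cells (349 CPM). At that stage DMRT1 UMIs lay mostly in germ cells in FTP (91 of 107, at 21.9 CPM) and in supporting cells in MTP (520 of 857, at 79.0 CPM). These counts follow class size, as the supporting class held 0.195% of the UMIs at stage 21 FTP. In the germ class DMRT1 was 1.99-fold higher in MTP at stage 21 (counting interval 1.31 to 2.97). DMRT1 was also higher in MTP in supporting cells, and the share of RNA from other cells was not computed for germ cells. The ratio is therefore not read as a difference made by germ cells. GLDN, which fell in MTP supporting cells, lies next to CYP19A1 in RefSeq. Clusters kept out of the classes included number 36, with 140 cells at stage 21 FTP and 10 at stage 21 MTP, and number 37, with 0 and 103.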
